A study of Homo sapiens with 8 samples.

How the data were processed

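Gene expression was measured on 8 1-colour Affymetrix arrays in MT-1 cells, a line derived from adult T cell leukaemia (ATL), and MT-2 cells, a T cell line infected with HTLV-1, the virus behind ATL. Each line was left untreated or received OR21, a DNA demethylating agent, EPZ-6438 (tazemetostat), an inhibitor of the histone methyltransferase EZH2, or both. Per the labels' protocols, MT-1 received 500 nM OR21 and 2500 nM EPZ-6438, MT-2 received 100 nM and 500 nM, cells were exposed for 96 h, and each compound was added at seeding and again at 48 h. DNase-treated total RNA was used and the fragmented single-stranded cDNA carried biotin, also per the labels' protocols. There was 1 array per line and treatment, so no condition was replicated within a line, and the number of arrays limits the precision.

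The deposited table holds log2 values of the 8 arrays, made with RMA (background correction, normalization between arrays and summary of the probes of a probe set), per the labels' processing tools. The version of RMA, the annotation release and the name of the array build are not given in the sources used here. The table itself does not state its log base, and base 2 is taken from the use of RMA. Its values ran from 2.14 to 18.91 with 0 missing values. The highest lie above 16, the most a 16-bit scanner gives on a log2 scale, and whether a rescaling followed RMA is not given in the sources used here. Every log2 difference and bound below rests on the scale being log2 as deposited. Of its 24351 entries, 2903 control probe sets were left out (2197 positive controls, 612 negative controls, 63 ERCC spikes and 31 AFFX controls), which left 21448 transcript probe sets. A platform annotation table gave exactly 1 gene symbol for 17709 of these, several for 0 and none for 3739, and all 17709 Entrez identifiers were found in the reference gene table, with 0 symbols updated.

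A probe set was kept where its highest value over the 8 arrays reached the median of the table, 6.573, which left 12942 probe sets, 11025 of them named. The 95th percentile of the negative-control probe sets of each array, between 7.19 and 7.80, stood for its background. Where the level lay above it on only 1 of the arrays compared, the difference was taken against the background level and is given as "at least" (or as a value "or lower"), and where it lay above on neither, or did not exceed the background of both arrays, no difference is given and the signal is called not above background. This use of the background level was added after the values were seen.

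All choices that follow, except where marked, were made before the data were examined. Per line, probe sets that differed from the untreated array of the line by 1 log2 unit or more were counted, with no test. Across lines, limma 3.58.1 (R 4.3.3; lmFit and eBayes, no trend) fitted cell line and treatment to all 8 arrays, with 3 residual degrees of freedom, and probe sets with a Benjamini-Hochberg adjusted p under 0.05 were called. The spread in this fit is the difference between the lines' responses and includes their different doses. The 647 probe sets expected by chance at an unadjusted p under 0.05 assume evenly spread p-values. This shared spread does not assure that, so 647 is only a rough mark. The combination was set against the sum of the log2 changes of the single agents (combination minus OR21 minus EPZ-6438 plus untreated), called the excess. A moderated F test of the 3 treatments was set against all 24 ways of pairing the arrays of 1 line with those of the other, and its count at an unadjusted p under 0.05 was chosen after the values were seen. Responses of the lines were compared by Pearson and Spearman correlation across probe sets. Probe sets are not independent replicates, so no p is given for these.

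The 20 gene lists were cancer-testis and germline genes; interferon-stimulated genes; endogenous retroviral envelope genes; antigen presentation, class I and class II; PRC2 components and H3K27 demethylases; DNA methylation machinery; Polycomb-target developmental regulators; genes reported silenced in T cell leukaemia; p53 targets; proliferation; BCL2 family; ATL phenotype genes; T cell identity and receptor signalling; NF-kappaB targets; markers of B cells, myeloid cells, NK cells and erythroid cells; epithelial, endothelial and fibroblast markers; integrated stress and unfolded protein response; cholesterol biosynthesis; and reference genes. Per line, the median change of a list was ranked among 10000 random lists of the same size matched on mean expression, as a description of these arrays. Across lines, camera in limma (correlation between genes preset at 0.01) compared each list with all other genes, adjusted over the 19 lists with at least 3 members tested in each treatment. Members called were also counted with p adjusted over the list alone.

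Genes were named by a fixed rule: up to 10 higher and 6 lower genes ranked by the smaller of the changes of the lines, the 3 highest and 2 lowest of each line, up to 4 members of each list described, the 5 highest and 5 lowest for the excess and for the untreated lines, and a panel of 19 genes of the epigenetic machinery and of ATL. Of the genes this rule gave with the combination, 2 are not reported here. HLA-DQA1 in untreated cells, CIITA, HLA-DPB1 and HLA-DMA with EPZ-6438, the lower NF-kappaB targets with OR21, and BAD and BCL2L11 with the combination were named after their values were seen. Where several probe sets carried a symbol, the brightest stood for it in the lists. The alternatives were no filter, a filter at the 75th percentile of the table, centring each array on its median, cyclic loess between arrays, a size of 1.5, 1 probe set per gene, an intensity trend in eBayes, an adjusted p under 0.10, no term for cell line, an estimated correlation between genes in camera, fry in place of camera, Spearman correlation, and leaving out each array in turn. Keeping probe sets above the background of at least 1 array was added after the values were seen.

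The scripts' statistics were tested on simulated data. With 200 of 12942 probe sets changed alike in both lines for OR21 against untreated, limma recovered 0% at a log2 change of 1, 85% at 2 and 99.5% at 4. Unchanged probe sets called numbered 1, 15 and 18. Camera called 1 of 50 simulated lists without a change and 50 of 50 shifted by 0.5. The noise of each simulated probe set was drawn independently, so camera was not tested on lists whose genes vary together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9 from tables made with pandas 2.3.3 and numpy 2.4.6.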

Results

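The arrays measured 21448 transcript probe sets in 2 T cell lines under 4 treatments, with 1 array in each of the 8 groups. Array medians lay between 6.44 and 6.68 on the log2 scale, and between 8126 and 9718 probe sets per array stood above the background level of the negative controls. Across genes, arrays of the same line correlated at r = 0.9554 to 0.9936 (12 pairs) and arrays of different lines at 0.8707 to 0.885 (16 pairs). No condition was replicated within a line, so differences within a line have no replicate error. All differences are in log2 units. The median change over the 12942 probe sets tested lay between -0.06 and -0.02 for the treatments in both lines.

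The untreated arrays showed what separated the lines before any compound was added. MT-2 cells carried far more signal for TNFRSF9, the T cell costimulatory receptor 4-1BB, than MT-1 cells (a difference of at least 8.85). The same held for the tetraspanin CD9 (at least 8.9), the actin-bundling protein FSCN1 (at least 9.21), the T cell transcription factor TOX (at least 8.02) and the calponin CNN3 (at least 7.61). MT-1 cells carried more signal for the costimulatory receptor CD28 (-4.99 or lower), for GTSF1, a germ cell factor of the piRNA pathway (-6.85 or lower), and for CYTIP (-6.26 or lower), RGS13 (-6.93 or lower) and GALNT14 (-4.67 or lower). Of the HLA class II list, HLA-DRA (-4.76), HLA-DPB1 (-5.42) and the transactivator CIITA (-4.78) were lower in MT-2, while HLA-DQA1 stood at 11.26 in MT-1 and 10.99 in MT-2. The list was not tested between the untreated lines. Among ATL phenotype genes, the adhesion molecule ICAM1 (at least 7.22) and TNFRSF18 (at least 4.56) were higher in MT-2, while the chemokine receptor CCR8 was lower (-5.42 or lower). The cancer-testis antigens CTAG2 (-4.24 or lower) and MAGEA4 (-5.02 or lower) were lower in MT-2, and CDKN1A, the cell cycle inhibitor p21, was higher (at least 4.95). MT-2 was higher by 1 or more in 2032 probe sets and lower in 3516, around a median difference of -0.295. With each array centred on its median these counts were 2712 and 2508, and with cyclic loess 2586 and 2500, so which line had more higher probe sets turned with the scaling.

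The comparison of OR21 with untreated cells asked what demethylation alone did. Germline genes that are normally shut outside the testis were among the genes with the highest values. The cancer-testis antigen SSX2B was higher by at least 7.0 in MT-1 and at least 1.4 in MT-2, and SSX1 by at least 6.41 in MT-1 and at least 0.3 in MT-2. In MT-1, GAGE12G was higher by at least 5.31, XAGE1B by at least 4.63, SSX5 by at least 3.49 and SSX3 by at least 1.07, and in MT-2 none of these 4 stood above background. SFN, the cell cycle checkpoint protein 14-3-3 sigma, was higher by 3.04 in MT-1 and at least 1.57 in MT-2. The histidine decarboxylase HDC was higher by at least 2.92 in MT-1 and at least 0.73 in MT-2, and the pluripotency factor SOX2 by at least 1.01 in MT-1 and at least 0.77 in MT-2. The glutathione transferase MGST1 reached at least 6.58 in MT-1, with no signal above background in MT-2. In MT-2 the chemokine CCL20 was higher by at least 1.75 and GTSF1 by at least 0.81. Members of the SSX, GAGE, XAGE and MAGEA families have near-identical copies, so their values are uncertain as to the single gene.

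Of the 23 cancer-testis and germline genes tested, 15 were higher by 1 or more in MT-1 (13 of them above background) and 7 in MT-2 (4 above background), 5 in both. Those 5 include members, such as MAEL, that did not stand above background in MT-2. The list rose as a set with OR21 (median 1.93 in MT-1 and 0.49 in MT-2, camera adjusted p = 6.94e-08; adjusted p = 0.409 with an estimated correlation). DAZL, a germ cell RNA-binding protein, was higher by at least 3.97 in MT-1, with no signal above background in MT-2. MAEL, which silences transposons in germ cells, was higher by at least 3.22 in MT-1, with no signal above background in MT-2. The 11 members without near-identical copies had medians of 1.93 in MT-1 and 0.43 in MT-2. With levels under background set to the background of each array, the list's medians were 0.81 in MT-1 and -0.24 in MT-2, the sign in MT-2 being that of the difference between the background levels. No member was called over all probe sets tested, and 0 adjusted over the list alone.

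Enzymes of cholesterol biosynthesis fell as a set with OR21, with 8 of 14 lower and 1 higher by 1 or more in MT-1 and 0 in MT-2 (medians -1.08 and -0.25, adjusted p = 0.00351; adjusted p = 0.567 with an estimated correlation). DHCR7, which makes cholesterol in the last step of the pathway, differed by -2.82 in MT-1 and -0.95 in MT-2, and the sterol sensor INSIG1 by -1.82 in MT-1 and -0.04 in MT-2. MVD differed by -2.05 in MT-1 and -0.2 in MT-2 and NSDHL by -1.59 in MT-1 and -0.27 in MT-2. The call was lost without the untreated MT-1 array (adjusted p = 0.0636) and without the MT-1 OR21 array (adjusted p = 0.313). The p53 targets rose as a set (medians 0.06 and 0.39, adjusted p = 0.00737; adjusted p = 0.409 with an estimated correlation), with 3 of 22 higher by 1 or more in MT-1 and 2 in MT-2. MDM2, which degrades p53, was higher by 2.01 in MT-1 and 0.5 in MT-2, TIGAR, a regulator of glycolysis, by 1.48 in MT-1 and 0.45 in MT-2, and CDKN1A by 0.56 in MT-2, with no signal above background in MT-1. The medians of this list were -0.06 in MT-1 and 0.21 in MT-2 where levels under background were set to it.

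Further lists had an adjusted p under the threshold with OR21 and lost it when single arrays were left out, each with adjusted p = 0.409 with an estimated correlation. NF-kappaB targets rose as a set (3 of 17 higher by 1 or more in each line, 2 lower in MT-1 and 0 in MT-2, medians 0.13 in MT-1 and 0.39 in MT-2, adjusted p = 0.0165). Its call was lost without the untreated MT-2 array (adjusted p = 0.359) and the MT-2 OR21 array (adjusted p = 0.143). The 2 lower members were CXCL8 (-1.09) and NFKBIE (-1.01 or lower). The cytokine IL6 was higher by 2.7 in MT-2, with no signal above background in MT-1. TNFAIP3, a brake on NF-kappaB, was higher by 1.66 in MT-1 and 0.38 in MT-2 and the chemokine CCL3 by at least 0.3 in MT-1 and 0.63 in MT-2. Interferon-stimulated genes rose as a set (1 of 22 higher by 1 or more in MT-1 and 2 in MT-2, 1 lower in MT-1, medians 0.20 and 0.29, adjusted p = 0.0165), a call lost without the untreated MT-1 array (adjusted p = 0.0952) and the MT-2 OR21 array (adjusted p = 0.281). USP18, which removes ISG15 from proteins, was higher by 1.18 in MT-1 and 0.37 in MT-2, and in MT-2 the viral RNA sensor DHX58 by at least 0.73 and IFIT3 by at least 0.51. Polycomb-target developmental regulators rose as a set (5 of 17 higher by 1 or more in MT-1, 0 of these above background, and 0 in MT-2, medians 0.47 and 0.11, adjusted p = 0.00271), lost without the untreated MT-1 array (adjusted p = 0.142). FOXF1 was higher by at least 0.15 in MT-1 and at least 0.76 in MT-2. Markers of B cells, myeloid cells, NK cells and erythroid cells moved with these groups, and the list rose (4 of 12 higher by 1 or more in MT-1 and 0 in MT-2, medians 0.45 and 0.29, adjusted p = 0.0252). Its call was lost without the untreated MT-1 array (adjusted p = 0.378) and the MT-1 OR21 array (adjusted p = 0.097). BLK, a kinase of B cells, differed by at least 3.62 in MT-1 and -0.75 in MT-2. With levels under background set to it, the medians in MT-1 and MT-2 were -0.16 and 0.38 for NF-kappaB targets, -0.16 and -0.11 for interferon-stimulated genes, and -0.16 and -0.24 for the Polycomb targets and for the markers. The -0.16 in MT-1 and the -0.24 in MT-2 equal the differences between the background levels of the arrays, so they are not measured falls.

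Among genes lower in both lines with OR21, the ubiquitin-binding adaptor CUEDC2 differed by -1.46 in MT-1 and -1.38 in MT-2 and the histone gene H2BC26 by -2.54 in MT-1 and -1.7 or lower in MT-2. PCBP3 differed by -1.61 in MT-1 and -1.39 in MT-2 and TTLL11 by -1.34 or lower in MT-1 and -1.25 or lower in MT-2. The rule also named NDUFS7, a subunit of respiratory complex I, but its fall was measured only in MT-1 (-1.49 or lower). In MT-2 it had no signal above background. The lowest of single lines were DHCR7 and PRKAR1B (-2.65 or lower in MT-1 and -0.22 in MT-2) in MT-1 and CXCL13, a chemokine that attracts B cells, in MT-2 (-2.18). In all, OR21 was followed by 692 probe sets higher and 485 lower by 1 or more in MT-1, and by 305 higher and 219 lower in MT-2. Of the higher ones, 442 in MT-1 and 156 in MT-2 stood above background on the OR21 array. With each array centred on its median, the MT-2 counts were 366 and 149. Across lines limma called 0 probe sets, with 1079 at an unadjusted p under 0.05 against 647 expected by chance. That count was 537 without the untreated MT-1 array, 604 without the MT-1 OR21 array, 511 without the MT-2 OR21 array, and 1726 without the combination array of either line.

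EPZ-6438 alone, the comparison that asked what EZH2 inhibition did, was followed by fewer differences of 1 or more than OR21. The prostaglandin-degrading enzyme HPGD was higher by 1.14 in MT-1 and 1.09 in MT-2, and LHFPL6 by 1.11 in MT-1 and 1.32 in MT-2. The hypoxia-inducible factor EPAS1 was higher by 0.97 in MT-1 and 0.89 in MT-2 and the calcium-binding protein family member S100A10 by at least 0.53 in MT-1 and 1.31 in MT-2. The chemokine gene CCL3 was higher by 1.85 in MT-2 and its near copy CCL3L3 by 2.1, as was TNFSF4, the ligand of the costimulatory receptor OX40 (2.11). In MT-1 the transcriptional regulator PRDM16 was higher by at least 2.35, EMP2 by at least 2.02, SSBP2 by 1.13, the heparan sulphate proteoglycan SDC3 by 0.98 and the receptor IL17RA by 0.92, and the potassium channel KCNQ3 was higher by 1.05 in MT-2.

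HLA class II antigen presentation genes rose as a set with EPZ-6438 (medians 0.67 in MT-1 and 0.18 in MT-2, camera adjusted p = 3.33e-05; adjusted p = 0.726 with an estimated correlation), with 1 of 10 higher by 1 or more in MT-1 and 0 in MT-2. HLA-DOA, which modulates peptide loading, was higher by 1.13 in MT-1, with no signal above background in MT-2. The antigen-presenting chains HLA-DRB1 (0.66 in MT-1 and 0.69 in MT-2), HLA-DPA1 (0.25 in MT-1 and 0.63 in MT-2) and HLA-DQB1 (0.68 in MT-1 and at least 0.18 in MT-2) were also higher. CIITA (0.83 in MT-1 and -0.31 in MT-2), HLA-DPB1 (0.84 in MT-1 and -0.13 in MT-2) and HLA-DMA (0.79 in MT-1 and -0.04 in MT-2) were higher in MT-1 and not in MT-2. Without the MT-1 EPZ-6438 array the adjusted p was 0.562. Genes reported silenced in T cell leukaemia (3 of 19 higher by 1 or more in MT-1 and 1 in MT-2, medians 0.27 and 0.09) and markers of B cells, myeloid cells, NK cells and erythroid cells (0 of 12 in MT-1 and 1 in MT-2, medians 0.34 and 0.13) each rose with adjusted p = 0.0476; adjusted p = 0.726 with an estimated correlation for both. The first of these lists held KLF2, a regulator of T cell quiescence and trafficking (1.3 in MT-1, with no signal above background in MT-2), PRDM1, which drives terminal lymphocyte differentiation (1.19 in MT-1 and 0.09 in MT-2), and the repressor ZEB1 (0.39 in MT-1 and 0.87 in MT-2). In the second, haemoglobin gene HBA1 was higher by at least 0.41 in MT-1, with no signal above background in MT-2. With levels under background set to it, medians in MT-1 and MT-2 were 0.67 and 0.12 for class II, -0.19 and 0.02 for the silenced genes and -0.19 and -0.37 for the markers. Here the -0.19 in MT-1 and the -0.37 in MT-2 equal the differences between the background levels of the arrays and are not measured falls. The call of the silenced genes was lost without the untreated MT-1 array (adjusted p = 0.937) and the MT-2 EPZ-6438 array (adjusted p = 0.976, with the direction turned). That of the markers was lost without the untreated MT-1 array (adjusted p = 0.867), the MT-1 EPZ-6438 array (adjusted p = 0.0975) and the MT-2 EPZ-6438 array (adjusted p = 0.433).

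Lower with EPZ-6438 were the cysteine desulphurase NFS1 (-1.06 in MT-1 and -0.79 in MT-2) and FAM174A (-0.3 or lower in MT-1 and -0.45 or lower in MT-2). In MT-1 the neutrophil chemokine CXCL8 differed by -1.73 and UNC93B1, which carries Toll-like receptors to endosomes, by -0.73. IFRD2 differed by -1.39 in MT-1 and 0.6 in MT-2, and the receptor kinase ROR2 by -0.95 in MT-2. The inhibitor was followed by 133 probe sets higher and 38 lower by 1 or more in MT-1 and by 116 higher and 46 lower in MT-2, and 75 of the higher ones in each line stood above background. Across lines limma called 0 probe sets, with 285 at an unadjusted p under 0.05 where 647 are expected by chance. That count was 159 without the OR21 array of either line, 175 without the MT-1 EPZ-6438 array and 149 without the MT-2 EPZ-6438 array.

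The comparison of the combination with untreated cells is the one the study's design text puts first, and more probe sets differed by 1 or more than with either agent alone in each line. SSX2B was higher by at least 8.02 in MT-1 and at least 2.33 in MT-2 and SSX1 by at least 7.15 in MT-1 and at least 1.69 in MT-2. CHI3L2, a chitinase-like secreted protein, was higher by at least 2.79 in MT-1 and at least 2.29 in MT-2. SFN was higher by 3.53 in MT-1 and at least 1.91 in MT-2 and the small GTPase RAB13 by at least 1.81 in MT-1 and at least 0.85 in MT-2. GAGE12G was higher by at least 7.1 in MT-1 and at least 0.04 in MT-2, and in MT-1 XAGE1B by at least 5.44 and the tetraspanin-like protein TM4SF1 by at least 1.93. GLUL, the glutamine synthetase, reached 13.87 in MT-1 from an untreated level of 4.57 (higher by at least 6.42), while in MT-2 it stayed at 11.72 against 11.72. In MT-2 the monocyte chemokine CCL2 was higher by at least 3.89, CCL20 by at least 3.14, CCL3L3 by 2.53 and GTSF1 by at least 1.98, the last in a line whose counterpart MT-1 already stood at 14.65 untreated.

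**Figure D1:**
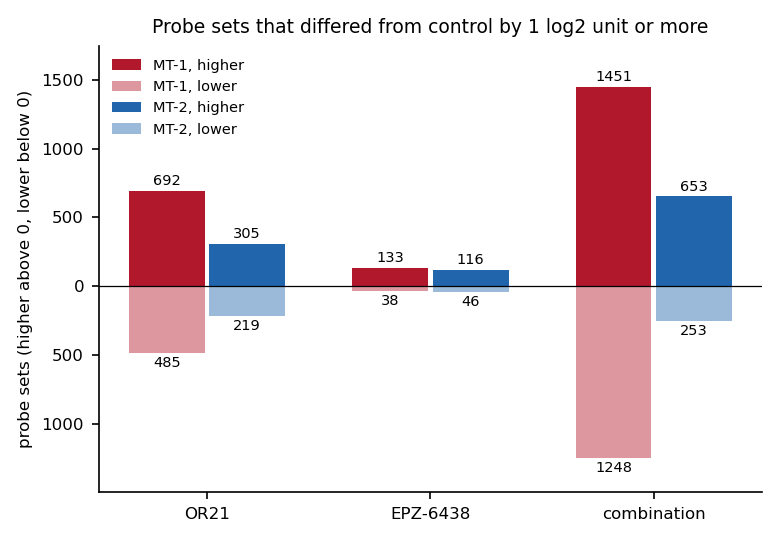
Bars count probe sets that differed from the untreated array of the same line by 1 log2 unit or more, higher ones above 0 and lower ones below 0, for MT-1 (red) and MT-2 (blue), with 1 array per bar and 1 untreated array per line. The combination gave the highest counts in both lines, 1451 higher and 1248 lower in MT-1 and 653 higher and 253 lower in MT-2.

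**Figure D2:**
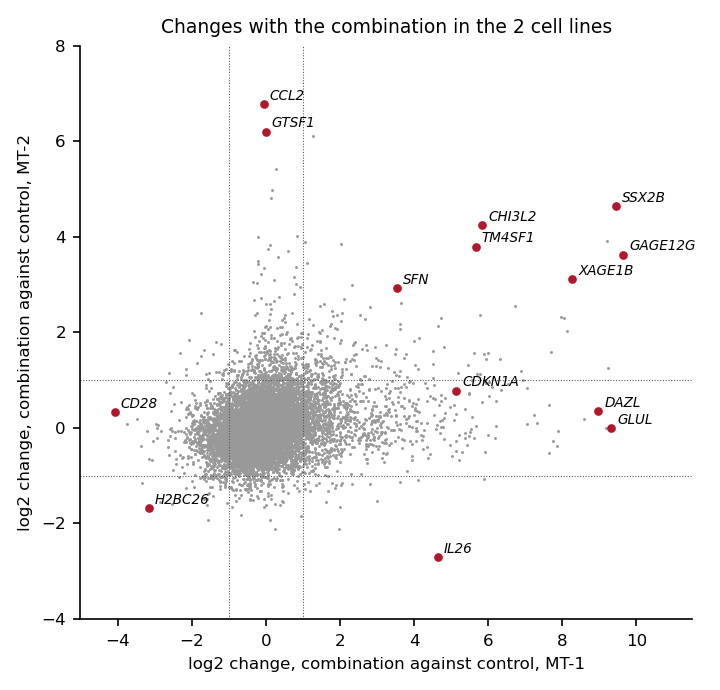
Each grey point is 1 of the 11025 probe sets with a gene symbol that passed the expression filter. It is placed by its log2 change with the combination in MT-1 (horizontal axis) and MT-2 (vertical axis). Labelled genes are in red, and dotted lines mark changes of 1 and -1. Across all 12942 probe sets past the filter, including those without a symbol that are not drawn, the changes correlated at r = 0.278. Changes from levels under background are drawn as measured.

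Cancer-testis and germline genes rose as a set with the combination (15 of 23 higher by 1 or more in MT-1, all 15 above background, and 7 in MT-2, 4 above background, 1 lower in MT-1, medians 3.11 and 0.40, camera adjusted p = 2.05e-05; adjusted p = 0.426 with an estimated correlation). DAZL was higher by at least 6.05 in MT-1, with no signal above background in MT-2 and MAEL by at least 4.23 in MT-1, with no signal above background in MT-2. With levels under background set to it, the medians were 0.96 in MT-1 and -0.17 in MT-2, the latter again the sign of the difference between background levels. Members called numbered 0 over all probe sets and 4 adjusted over the list alone. The 11 members without near-identical copies had medians of 3.11 and 0.26. Genes reported silenced in T cell leukaemia rose (12 of 19 higher by 1 or more in MT-1, 10 of them above background, and 3 in MT-2, 2 above background, 1 lower in MT-2, medians 2.13 and 0.13, adjusted p = 0.000452; adjusted p = 0.515 with an estimated correlation). Over all probe sets 0 members were called, and 3 adjusted over the list alone. Its call was lost without the MT-1 combination array (adjusted p = 0.0684). DUSP5, a phosphatase that switches off ERK signalling, was higher by at least 3.23 in MT-1 and 2.18 in MT-2. CDKN1A was higher by at least 2.0 in MT-1 and 0.78 in MT-2, and the ubiquitin ligase RNF130 differed by at least 1.08 in MT-1 and -0.56 in MT-2. LAIR1 did not stand above background in either line. The medians of the silenced genes were 0.85 in MT-1 and 0.02 in MT-2 where levels under background were set to it.

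The p53 targets rose (5 of 22 higher by 1 or more in MT-1 and 4 in MT-2, 1 lower in MT-1, medians 0.30 and 0.36, adjusted p = 0.00119; adjusted p = 0.292 with an estimated correlation). Of the 19 list calls, this 1 also passed the threshold in fry (adjusted p = 0.0173), a test of whether its genes move on balance 1 way. Adjusted over the list alone, 4 members were called, and 0 over all probe sets. MDM2 was higher by 2.54 in MT-1 and 1.02 in MT-2 and ZMAT3, an RNA-binding p53 target, by at least 0.58 in MT-1 and 1.51 in MT-2. Interferon-stimulated genes rose (9 of 22 higher by 1 or more in MT-1 and 3 in MT-2, 1 lower in MT-1, medians 0.76 and 0.39, adjusted p = 0.000155; adjusted p = 0.292 with an estimated correlation). In this list 1 member was called adjusted over the list alone and 0 over all probe sets. The antiviral membrane protein IFITM3 was higher by 1.8 in MT-1 and 0.41 in MT-2, and IFIT5 by at least 0.54 in MT-1 and at least 0.51 in MT-2. IFIT3 was higher by at least 0.35 in MT-1 and at least 0.42 in MT-2. NF-kappaB targets rose (4 of 17 higher by 1 or more in MT-1 and 5 in MT-2, 1 lower in MT-1, medians 0.22 and 0.51, adjusted p = 0.00569; adjusted p = 0.426 with an estimated correlation). Of its members 5 were called adjusted over the list alone and 0 over all probe sets. IL6 was higher by 3.09 in MT-2, with no signal above background in MT-1, and CCL3 by at least 3.45 in MT-1 and 1.56 in MT-2. The receptor adaptor TRAF1 was higher by 2.23 in MT-1 and 0.49 in MT-2 and lymphotoxin LTA by at least 0.36 in MT-2, with no signal above background in MT-1. With levels under background set to it, medians in MT-1 and MT-2 were 0.18 and 0.31 for p53 targets, 0.34 and -0.02 for interferon-stimulated genes and -0.27 and 0.51 for NF-kappaB targets. The -0.27 equals the difference between the background levels of the MT-1 arrays and is not a measured fall. The NF-kappaB call was lost without the untreated MT-2 array (adjusted p = 0.115) and the MT-2 combination array (adjusted p = 0.0566).

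Polycomb-target developmental regulators rose (8 of 17 higher by 1 or more in MT-1, 4 of them above background, and 2 in MT-2, 1 above background, medians 0.81 and 0.25, adjusted p = 0.000182; adjusted p = 0.292 with an estimated correlation). Adjusted over the list alone 3 members were called, and 0 over all probe sets. With levels under background set to it, the medians were -0.27 and -0.17, which equal the differences between the background levels of the arrays. The measured medians of this list therefore rest on signal at or near background. HOXD13, which patterns limbs, was higher by at least 1.6 in MT-1, with no signal above background in MT-2. HOXC10 was higher by at least 0.73 in MT-1, with no signal above background in MT-2, and the eye regulator PAX6 by at least 0.46 in MT-1 and 0.54 in MT-2. Markers of other cell types moved alongside. Epithelial, endothelial and fibroblast markers rose (5 of 8 higher by 1 or more in MT-1 and 0 in MT-2, medians 1.65 and 0.02, adjusted p = 0.00813; adjusted p = 0.515 with an estimated correlation), a call that was lost without the untreated MT-1 array (adjusted p = 0.121) and the MT-1 combination array (adjusted p = 0.38). The keratin KRT8 differed by 5.14 in MT-1 and -0.27 in MT-2, and in MT-1 KRT18 was higher by at least 1.64 and the adhesion molecule EPCAM by at least 1.2. Markers of B cells, myeloid cells, NK cells and erythroid cells rose (5 of 12 higher by 1 or more in MT-1 and 0 in MT-2, 1 lower in MT-2, medians 0.42 and 0.19, adjusted p = 0.034; adjusted p = 0.515 with an estimated correlation). This call was lost without the untreated MT-1 array (adjusted p = 0.193) and the MT-1 combination array (adjusted p = 0.333). HBA1 was higher by at least 2.55 in MT-1, the cytotoxic granule protein GNLY by at least 1.96 and S100A8 by at least 1.05. Set to background in the same way, the medians were 0.60 and -0.17 for the epithelial list and -0.19 and -0.17 for the blood cell markers. The -0.17 in MT-2 again equals the difference between background levels. In MT-1 that difference is -0.27, larger in size than the -0.19, which is therefore not a measured fall. Of the 12 blood cell markers, 0 were lower by 1 or more in MT-1.

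Cholesterol biosynthesis fell (7 of 14 lower by 1 or more in MT-1 and 1 in MT-2, 1 higher in MT-1, medians -1.03 and -0.34, adjusted p = 0.00317; adjusted p = 0.525 with an estimated correlation), and 0 members were called, adjusted over the list alone or over all probe sets. DHCR7 differed by -3.08 in MT-1 and -0.68 in MT-2 and MVD by -2.41 or lower in MT-1 and -0.26 in MT-2. NSDHL differed by -1.81 in MT-1 and -0.35 in MT-2 and the mevalonate kinase MVK by -1.27 in MT-1 and -0.97 in MT-2. Lists that did not pass the threshold with the combination were class II (adjusted p = 0.0775) and class I antigen presentation (adjusted p = 0.197), proliferation (adjusted p = 0.139), and the BCL2 family (adjusted p = 0.151). Others were ATL phenotype genes (adjusted p = 0.221), reference genes (adjusted p = 0.35), T cell identity (adjusted p = 0.447), DNA methylation machinery (adjusted p = 0.559), stress response (adjusted p = 0.736) and PRC2 components (adjusted p = 0.881). Adjusted over the list alone, 3 members of the T cell list, 2 of the ATL list and 1 of the stress list were called, against 0 over all probe sets. The endogenous retroviral list had 2 members on the array past the filter and was not tested.

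**Figure D3:**
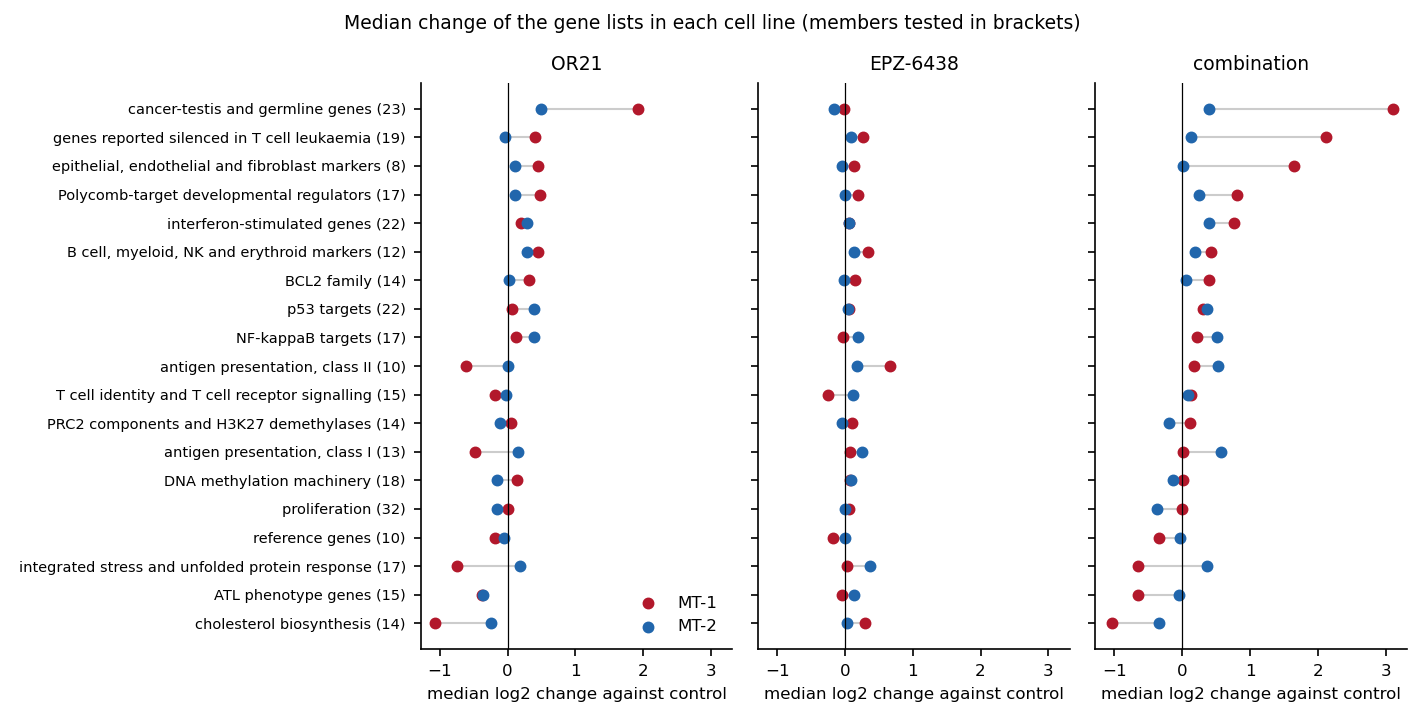
Points give the median log2 change of each gene list in MT-1 (red) and MT-2 (blue) for OR21, EPZ-6438 and the combination, with the number of members tested in brackets and 1 array per line and treatment. The cancer-testis and germline list stands farthest to the right with the combination in MT-1 (3.11) and cholesterol biosynthesis farthest to the left (-1.03).

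The lists of stress and growth genes ran differently in the lines. Genes of the integrated stress and unfolded protein response had a median of -0.65 in MT-1, where 8 of 17 were lower by 1 or more, and of 0.37 in MT-2, where 4 were higher by 1 or more. TRIB3 differed by -2.03 in MT-1 and -0.32 in MT-2 and PHGDH, the entry enzyme of serine synthesis, by -1.11 in MT-1 and -0.05 in MT-2. SDF2L1 differed by -1.39 in MT-1, with no signal above background in MT-2, and XBP1, a transcription factor of the unfolded protein response, by -0.47 in MT-1 and 1.65 in MT-2. Proliferation genes had a median of 0.00 in MT-1 and -0.37 in MT-2. Members were the replication helicase subunits MCM2 (-0.12 in MT-1 and -1.31 in MT-2) and MCM6 (-0.57 in MT-1 and -1.28 in MT-2) and the cell cycle factor E2F1 (-0.83 in MT-1 and -0.27 or lower in MT-2). The difference between the lines was not tested for either list.

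In the panel of epigenetic and ATL genes, the oncogene MYC was lower with the combination in both lines (-2.21 in MT-1 and -0.95 in MT-2). CCR4, a chemokine receptor of ATL cells, differed by -1.6 in MT-1 and 0.16 in MT-2. The target of the inhibitor, EZH2, differed by 0.31 in MT-1 and -0.29 in MT-2 and its partner SUZ12 by -0.12 in MT-1 and -0.85 in MT-2. DNA methyltransferase DNMT1 differed by -0.22 in MT-1 and -0.86 in MT-2, and DNMT3A by 0.37 in MT-1 and 0.79 in MT-2. DNMT3B differed by at least 0.3 in MT-1, with no signal above background in MT-2. UHRF1, which guides DNMT1 to replicating DNA, differed by 0.45 in MT-1 and -1.55 in MT-2. ZEB1 differed by -0.3 in MT-1 and 0.13 in MT-2, the interleukin 2 receptor chain IL2RA by -0.79 in MT-1 and 0.27 in MT-2 and the adhesion molecule CADM1 by 0.87 in MT-1 and -0.06 in MT-2. FOXP3 and THEMIS did not stand above background, and EED and NDRG2 were not named for any probe set.

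**Figure D4:**
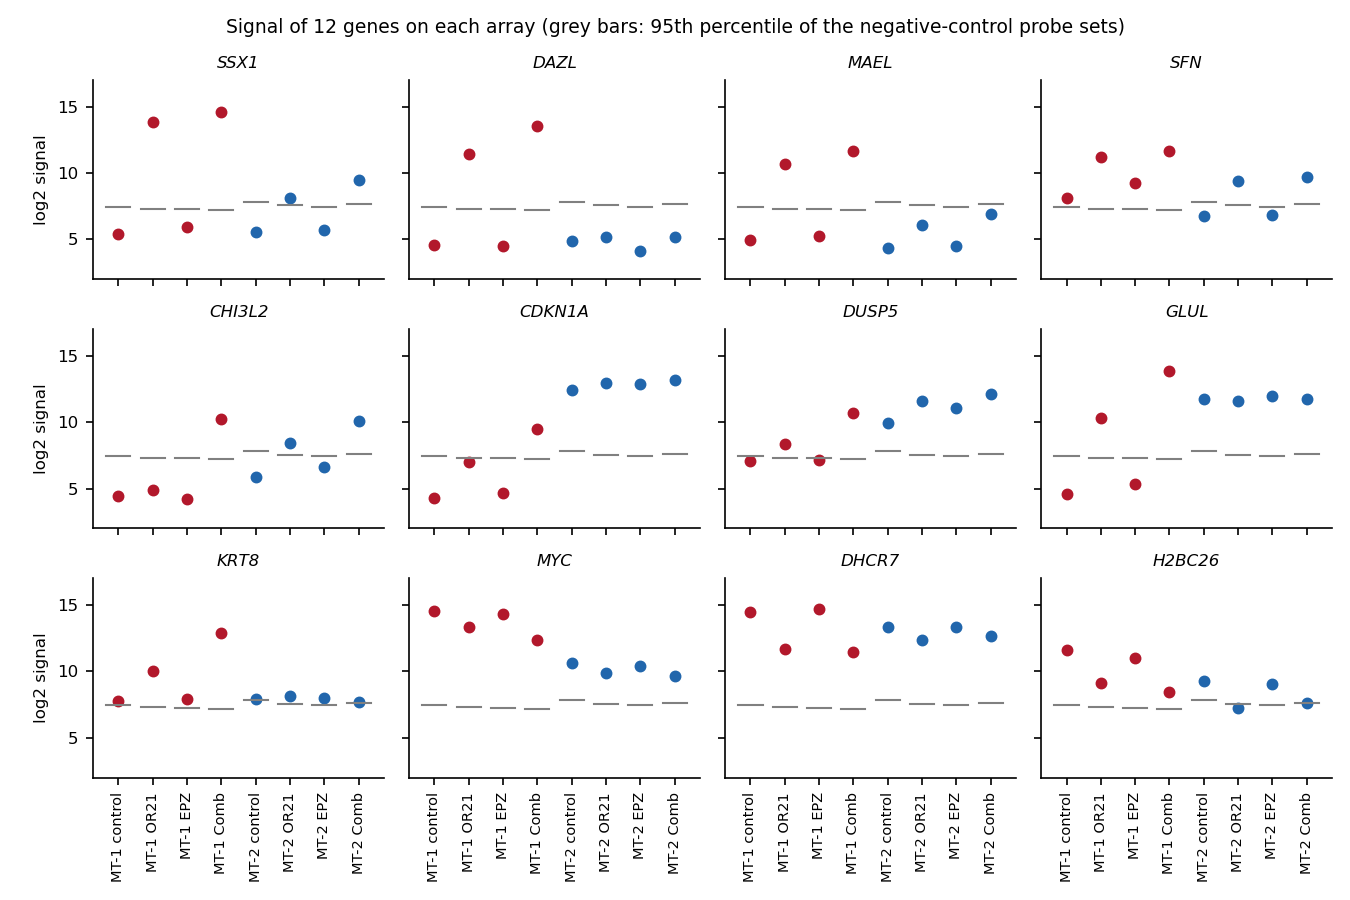
Points show the log2 signal of 12 genes on the 8 arrays, MT-1 in red and MT-2 in blue, and grey bars mark the 95th percentile of the negative-control probe sets of each array. CHI3L2 reached 10.24 in MT-1 and 10.09 in MT-2 with the combination, while MYC went from 14.54 to 12.33 and from 10.62 to 9.67.

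Lower in both lines with the combination were the kinase CAMKK2, which activates AMPK (-1.67 in MT-1 and -1.5 in MT-2) and the mitochondrial chaperone TRAP1 (-2.52 in MT-1 and -1.58 in MT-2). So were H2BC26 (-3.16 in MT-1 and -1.63 or lower in MT-2), FAM216A (-2.85 in MT-1 and -0.73 or lower in MT-2) and the ubiquitin ligase RFFL (-1.55 in MT-1 and -1.87 or lower in MT-2). CD28 in MT-1 differed by -4.08, MANEAL by -3.75 and TNIP3 in MT-2 by -1.39 or lower. Counts of probe sets that differed by 1 or more were 1451 higher and 1248 lower in MT-1 and 653 higher and 253 lower in MT-2, and 1152 and 477 of the higher ones stood above background with the combination. From a level not above background in untreated cells came 649 of these in MT-1 and 216 in MT-2. Across lines limma called 0 probe sets, with 2489 at an unadjusted p under 0.05 (1189 higher and 1300 lower) against 647 expected by chance. The lowest adjusted p was 0.114, the value for SFN, RAB13, TM4SF1, ZMAT3 and CAMKK2, among others. Without the MT-2 combination array limma called 740 probe sets, a fit in which the lone MT-1 combination array is assumed to vary like the other groups, and with an intensity trend it called 10. The count at an unadjusted p under 0.05 was 1234 without the untreated MT-1 array and 1519 without the MT-1 combination array.

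The series set out to find the combined effect of the agents, so the combination was also set against each agent alone. CHI3L2 in MT-1 stood at 10.24 with the combination and, with no signal above background, at 4.9 with OR21 and 4.2 with EPZ-6438. TM4SF1 stood at 9.39 with the combination, against 4.8 and 3.97, both under background. GLUL reached 13.87 against 10.31 with OR21. In MT-2, CCL2 stood at 11.7 with the combination and under background with OR21 (6.73) and EPZ-6438 (5.7). SSX2B, in contrast, stood at 14.46 with OR21 alone and 15.47 with the combination in MT-1. Against OR21 limma called 0 probe sets across lines (917 at an unadjusted p under 0.05) and against EPZ-6438 it called 0 (1373 at an unadjusted p under 0.05). Without the MT-2 combination array the calls were 72 against OR21 and 231 against EPZ-6438, and the counts at an unadjusted p under 0.05 were 1816 and 2942. The count against OR21 was 444 without the MT-1 OR21 array and 422 without the MT-2 OR21 array, and that against EPZ-6438 was 428 without the MT-1 EPZ-6438 array.

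Beyond the sum of the single agents, the rule for the excess named on the higher side TM4SF1 (4.36 in MT-1 and 1.49 in MT-2), the laminin-related guidance protein NTN4 (3.24 in MT-1 and 1.58 in MT-2) and the actin-capping protein CAPG (2.65 in MT-1 and 1.55 in MT-2). It also named the cancer-testis antigen GAGE13 (1.65 in MT-1 and 2.26 in MT-2) and the gonadal transcription factor DMRT1 (1.59 in MT-1 and 1.46 in MT-2). On the lower side it named ZNF875 (-1.35 in MT-1 and -1.08 in MT-2), ZNF678 (-1.32 in MT-1 and -1.0 in MT-2), CLDND2 (-1.13 in MT-1 and -1.08 in MT-2) and QRFP (-1.08 in MT-1 and -1.3 in MT-2), and JAKMIP3, which stood above background on 0 of the 8 arrays. Of these 10 genes only QRFP stood above background on all 8 arrays, so the other values include signal at or under background, and their order is not meaningful. The excess was 1 or more in 686 probe sets and -1 or lower in 256 in MT-1, and in 314 and 211 in MT-2. With each array centred on its median the counts were 578 and 339 in MT-1 and 219 and 292 in MT-2, which turned the balance in MT-2. With cyclic loess they were 737 and 214 in MT-1 and 297 and 214 in MT-2. Limma called 0 probe sets for the excess across lines, with 223 at an unadjusted p under 0.05 where 647 are expected by chance. Without the MT-2 combination array it called 7, with 886 at an unadjusted p under 0.05. That count was 549 without the MT-1 combination array, 86 without the MT-1 EPZ-6438 array, 147 without the MT-1 OR21 array and 139 without the MT-2 OR21 array. No gene list passed the threshold for the excess, the lowest adjusted p being 0.0807.

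How far the lines shared a response was asked of the genes that differed by 1 or more in both. With the combination 232 probe sets were higher in both lines, among them SSX2B, SSX1, CHI3L2 and SFN, where 73.2 are expected for independent lists. Another 60 were lower in both, among them CAMKK2 and TRAP1, where 24.4 are expected. For OR21 these counts were 82 higher (16.3 expected) and 29 lower (8.2 expected), and for EPZ-6438 6 higher (1.2 expected) and 1 lower (0.1 expected). All these counts include changes whether or not the level stood above background, and near-identical copies such as SSX and GAGE genes count separately. The expected numbers are therefore only a rough mark. Across probe sets, changes in MT-1 and MT-2 correlated at r = 0.277 for OR21, 0.119 for EPZ-6438 and 0.278 for the combination, with Spearman coefficients of 0.232, 0.119 and 0.233. Probe sets are not independent replicates. Changes with the combination in MT-1 also correlated with those of OR21 in MT-2 (r = 0.272) and less with those of EPZ-6438 in MT-2 (r = 0.089), with Spearman coefficients of 0.243 and 0.122. In the other direction, changes with the combination in MT-2 correlated with those of OR21 in MT-1 at r = 0.202 and of EPZ-6438 in MT-1 at r = 0.124. The Spearman coefficients there were 0.104 and 0.122, in the opposite order. The 2 lines share no array, and doses were 5 times as high in MT-1, so line and dose are not separate in these comparisons.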

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

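The tests of carry-over between lines and of noise shared by the treatments, the shares past the expression filter, the rescaled ratios, and the count at an unadjusted p used to compare pairings, were chosen only after the result was seen. Genes that moved as measured by 1 log2 unit or more in opposite directions in the lines drew attention, and none of these differences between the lines was tested. With the combination, BLK, a kinase of B cells, was higher by 3.62 in MT-1, from a level under background (at least 2.87 above it), and differed by -1.13 in MT-2. IL26, a cytokine of T cells, was higher by 4.64 in MT-1 from a level under background (at least 2.31) and differed by -2.7 in MT-2, where it ended under background (-2.0 or lower). CHAC1, a glutathione-degrading enzyme of the stress response, differed by -1.03 in MT-1 and 1.35 in MT-2 with the combination, and by -1.18 and 1.02 with OR21, the MT-2 values from a level under background (at least 1.26 and at least 0.93). The endogenous retroviral envelope gene ERVV-1 differed by -1.74 in MT-1 and by 1.5 in MT-2 with the combination. It ended under background in MT-1, where the difference above background is -0.42 or lower, so a move of 1 or more is not measured there.

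In MT-1 the combination was followed by higher signal for genes that MT-2 already expressed. All 17709 named probe sets entered this comparison, with no expression filter. Of 741 at background in untreated MT-1 and above it in untreated MT-2, 273 (36.84%) were higher by 1 or more, against 818 of 9153 (8.94%) at background in both lines, a ratio of 4.122. RNA of MT-2 carried into the MT-1 combination array is argued against. The share needed for the median gene of the pattern is 20.8%. The test took the 23 transcripts at 14 or more with the combination in MT-2 and at background in untreated MT-1. Of these, 86.96% lay more than 1 log2 unit under what that share would give. Their median in MT-1 still rose from 5.299 untreated to 8.496 with the combination. Of the 23, 7 stayed at background there, among them TNFRSF9 (5.74, against 16.47 in MT-2). Those 7 allow a share of at most 0.824%, and 260 of the 273 genes of the pattern exceeded what that share adds. Noise of the untreated MT-1 array, which the treatments share, would act alike on all of them. It does not account for the size of the share with the combination, which was 9.1 times that with EPZ-6438 (4.05%). The preference for genes expressed in MT-2 was not particular to the combination, however. In MT-1 it was 18.49% against 4.39% with OR21 and 4.05% against 0.86% with EPZ-6438. The test by shares therefore does not decide whether that noise adds to the preference. Probe sets that give no signal in any cell and dilute the comparison group stay open. Within the MT-2-expressed genes, where dilution predicted equal shares, the upper part by MT-2 level was higher 2.647 times as often as the lower part (53.51% against 20.22%). But of the 9153 only 2469 passed the expression filter, and 22.52% of these were higher, a ratio of 1.636 for all 741. The lower part did not exceed that share, so the difference between the parts does not decide the question. That filter keeps probe sets for their treated level too, which raises the 22.52%. Among the 1559 that reached the filter level in untreated cells 11.23% were higher, a ratio of 3.282. The same ratio in MT-1 was 3.066 with OR21 and 3.322 with EPZ-6438. These 1559 still stood at background in both untreated lines, so probe sets without signal may remain among them. The mirror comparison in MT-2 gave 7.57% against 3.32% (a ratio of 2.279), but 9.32% (a ratio of 0.812) among probe sets past the filter. Among those that reached the filter level in untreated cells the comparison share was 5.71% (a ratio of 1.326). The direction in MT-2 thus turned only with the filter that also keeps probe sets for their treated level. A greater response of genes shut in 1 line and open in the other, and dilution by silent probe sets, cannot be told apart here.

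The excess of the combination over the sum of the agents in MT-1 leaned upward, with 2.68 values of 1 or more for each of -1 or lower. With each array centred on its median this ratio was 1.705 (578 against 339), and with cyclic loess 3.444 (737 against 214). The floor of the signal scale, which hides falls, stays open: among 8483 probe sets above background on all 4 MT-1 arrays the ratio was 2.022 (184 against 91), but 1.163 (143 against 123) with centred arrays and 2.122 (191 against 90) with cyclic loess. The test of noise in the untreated MT-1 array decided nothing: combination minus OR21, which leaves that array out, gave 4.173 (747 against 179), but it keeps the change with EPZ-6438, which leaned upward itself (133 against 38). The scaling, the floor, noise of single arrays and an effect of the agents beyond their sum cannot be told apart here, because no array is repeated.

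Whether the lines share a response was asked by pairing the treatments of the lines in other ways. The moderated F test gave 1281 probe sets at an unadjusted p under 0.05 (0 after adjustment) with the real pairing of treatments, and of the 24 pairings only this 1 gave as many, the highest other giving 989. After adjustment all 24 pairings gave 0, so that count separated nothing. On the count at an unadjusted p the share was under 0.05, the real pairing being 1 of 24, the smallest share possible here. That count was chosen after the values were seen, so it does not exclude chance pairing. Line and dose stay confounded in this comparison.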

How the results depend on the processing

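The filter on the background of at least 1 array was chosen only after the result was seen. Counts of limma calls stayed at 0 in all 6 contrasts under every filter, scaling and threshold tried and with no replicate block (cell line left out). The exceptions were the intensity trend, which gave 10 for the combination against untreated, and the arrays left out. Leaving out single arrays gave 0 to 740 for that contrast, 0 to 72 against OR21, 0 to 231 against EPZ-6438 and 0 to 7 for the excess, each upper value without the MT-2 combination array. Counts by size in the order of MT-1 OR21, EPZ-6438 and the combination, then MT-2 in the same order, higher then lower, depend on the thresholds by construction. At the 75th percentile filter, which tests fewer probe sets, they were 356 and 273, 61 and 13, 806 and 829, 149 and 111, 61 and 12, and 377 and 158, with 345 and 75 for the excess in MT-1, 108 and 55 in MT-2, and 1011 higher in untreated MT-2. At a size of 1.5 they were 346 and 97, 31 and 1, 877 and 384, 97 and 20, 15 and 3, and 252 and 30, with 315 and 25, 48 and 21 for the excess, and 2070 lower in untreated MT-2. Without a filter, which tests more probe sets, EPZ-6438 in MT-2 gave 89 lower, the excess in MT-1 458 at -1 or lower, and in MT-2 494 and 445, and with the background filter the last was 137. Correlations between lines were 0.088 (no filter) and 0.181 (75th percentile) for EPZ-6438, 0.32 (75th percentile) and 0.233 (Spearman) for the combination and 0.232 (Spearman) for OR21, and the cause was not tested. All 19 list calls were lost with an estimated correlation, which widens the test: with OR21 the adjusted p was 0.409, and 0.567 for cholesterol biosynthesis. With EPZ-6438 it was 0.726, and with the combination 0.292 (interferon, Polycomb, p53), 0.426 (cancer-testis, NF-kappaB), 0.515 (silenced genes and both marker lists) and 0.525 (cholesterol). With fry, which does not compare a list with other genes, 18 were lost: with OR21 0.367 (cancer-testis, Polycomb), 0.152 (p53) and 0.474 (the other 4), with EPZ-6438 0.955, and with the combination 0.107 (interferon, Polycomb), 0.209 (cancer-testis, NF-kappaB) and 0.253 (the other 4). The other list calls that were lost, with the cause not tested, were these. Without a filter, EPZ-6438 silenced genes 0.0565 and blood cell markers 0.0748, and with the background filter 0.0924 for each. At the 75th percentile filter, OR21 interferon 0.33, Polycomb 0.149 and blood cell markers 0.0616, and blood cell markers with EPZ-6438 0.565 and with the combination 0.107. With cyclic loess, OR21 interferon 0.1 and blood cell markers 0.138, EPZ-6438 silenced genes and blood cell markers 0.0788 each, and blood cell markers with the combination 0.0923. Leaving out single arrays, the adjusted p ranged from 0.000916 to 0.281 for interferon, 0.00102 to 0.142 for Polycomb, 0.00444 to 0.378 for blood cell markers, 5.87e-06 to 0.313 for cholesterol and 0.000325 to 0.359 for NF-kappaB with OR21. The range was 0.000648 to 0.976 for silenced genes (direction turned without the MT-2 EPZ-6438 array), 0.0119 to 0.867 for blood cell markers and 1.56e-10 to 0.562 for class II with EPZ-6438. It was 0.00267 to 0.333 for blood cell markers, 0.000113 to 0.38 for epithelial and related markers, 3.58e-06 to 0.0684 for silenced genes and 0.00036 to 0.115 for NF-kappaB with the combination. The median of T cell identity genes with EPZ-6438 in MT-1, -0.256, became 0.002 without a filter and 0.083 at the 75th percentile. Mean changes over the lines of genes that were not called turned sign when single arrays were left out, with the range for OR21 of -1.92 to 0.072 for CXCL13 and -0.14 to 1.44 for PAX6. For EPZ-6438 it was -1.50 to 0.70 for IFRD2, -0.19 to 1.24 for HBA1, -0.34 to 1.66 for KLF2 and -0.13 to 1.41 for PRDM1. For the combination it was -2.11 to 4.05 for IL26, -0.48 to 2.97 for BLK, -0.22 to 1.41 for XBP1, -0.18 to 3.03 for HOXD13, -0.21 to 0.22 for EZH2, -0.67 to 0.16 for IL2RA, -1.26 to 0.16 for UHRF1 and -0.28 to 0.11 for ZEB1, and -0.17 to 4.09 for the excess of GAGE13. EZH2 was -0.015 with arrays centred on their medians and ZEB1 0.04 with cyclic loess. Direction and side of the threshold were kept by 211 of the list results and 1771 of the values of named genes, where values between untreated lines counted if they moved within their spread. Part of this was fixed by the design. Leaving out the term for cell line, or an array outside a comparison of 1 treatment with untreated, cannot change the mean change. No gene was called over all probe sets, so the side of the threshold could change only by a new call. Of the other named values that kept their direction, 37 passed the threshold without the MT-2 combination array, and 45 between untreated lines moved with the scaling by more than their spread, as 60 list medians of single lines did with filter or scaling. Signal over background sets the limit: 8126 to 9718 of 21448 probe sets per array stood above it. No fit with replicates within a line can be made from 1 array per condition.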

Other observations

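Lists that did not pass the threshold with the combination still held members far from their untreated level. IL2RB, a chain of the interleukin 2 receptor, was higher in MT-1 by at least 5.15 and differed by -0.02 in MT-2, and CCR8, a chemokine receptor of regulatory T cells, differed by -2.9 in MT-1. Of the death-promoting BCL2 family members, BID and PMAIP1 were higher, BID by at least 2.98 in MT-1 and 0.23 in MT-2, and PMAIP1 by 2.41 in MT-1 and 0.56 in MT-2. Of other death-promoting members, BAD was lower (-1.16 in MT-1 and -0.23 in MT-2) and BCL2L11 differed by 0.85 in MT-1 and -1.11 in MT-2. LEF1, a transcription factor of T cell development, was higher by 2.04 in MT-1 and 1.24 in MT-2, while CD247, the zeta chain of the T cell receptor complex, differed by -2.16 in MT-1 and -1.25 in MT-2. None of these genes was called by limma over all probe sets.

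Class I antigen presentation genes in MT-2 had a median change of 0.57 with the combination, at the 99.99th percentile of matched random lists, against 0.01 in MT-1. The list did not pass the threshold across lines (adjusted p = 0.197).

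Among the 11016 genes past the expression filter, genes higher by 1 or more in MT-1 with the combination were often neighbours on chromosomes. Related symbols left out, 177 neighbouring pairs were both higher, against a mean of 140.85 in 1000 shuffles (permutation p = 0.002, where the smallest the shuffles can give is 0.001). In MT-2 there were 37 such pairs against 29 (permutation p = 0.0699). The filter also keeps genes for their treated level, so genes that stayed silent are missing from the order and raised genes can become neighbours. Shuffling the calls does not remove this, so the count does not show adjacency beyond chance. That stretches of chromatin may open together remains a hypothesis, looked at here only through the order of genes in the reference.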
